A study of Mus musculus with 2 samples.

How the data were processed

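Total RNA was sequenced from primary neutrophils of the spleen of adult male mice at 65 days. The mice were B6CASTF1/J, the F1 hybrid of a C57BL/6 mother and a CAST/EiJ father. The labels give 1 group with 2 libraries, called biological replicates 1 and 2, each made from 300 ng of RNA with ERCC spike-in RNA added and, per the labels, with a directional library kit. Both libraries carry the same donor identifier, so the labels do not show that they came from separate animals, and the spread between them may be technical in part.

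Each library came with 3 tables. The gene table and the first transcript table have the column layout that RSEM writes. They hold expected counts and TPM, which the authors derived from transcriptome alignments to mm10 with GENCODE M21. The program, its version and the aligner are not given in the sources used here. In these tables the deposited TPM values sum to the same total in each library over all entries, with tRNA, spike-in and phiX entries included, and the effective length is the length minus 100 nt. For the 28694 transcripts of 100 nt or less it is 0, and these held 0 expected counts in both libraries, so their levels cannot be read from these tables. The deposited FPKM of the gene table is scaled by effective length and by sequencing depth, and it served only as an alternative unit. The second transcript table has the column layout that kallisto writes. It holds estimated counts and TPM, which the authors derived directly from the FASTQ file, per the files' accompanying notes, with the same build and annotation. Its effective lengths lie a median of 227 nt (replicate 1) and 252 nt (replicate 2) below the length in transcripts over 1 kb. These quantifications are called RSEM and kallisto below for their layouts.

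All 55536 Ensembl genes of the gene table matched the annotation. The tables also hold 26248 tRNA entries and 96 ERCC entries. A set of 86 genes on unplaced scaffolds has no transcript in the kallisto table. Total expected counts were 18387963 in replicate 1 and 18090108 in replicate 2. Given the length-scaled sum over all entries of each library, 1 count on a gene of 1 kb of effective length corresponds to 0.0458 and 0.0538 TPM. A count of 0 allows up to 3 counts. These limits and the binomial test cover counting error only, since reads without molecular identifiers are not independent molecules.

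Gene levels are the deposited RSEM TPM, given as the mean and SD of n = 2. There is 1 group, so no test between conditions exists and none was made. A total of 31 gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. List medians are printed as the mean and SD of the medians of both libraries. Each list's median of the mean TPM was placed among the medians of 10000 random lists of the same size, drawn from protein-coding genes with TPM above 0 in either library. A list counts as above or below random lists when its percentile lies outside the central 95%. Differences between lists were taken on log2(TPM + 0.1) within each library. Correlations are across genes with TPM above 0 in either library, and genes are not independent replicates. The biological coefficient of variation came from edgeR with an intercept-only design on rounded expected counts with TMM scaling, for genes with at least 10 counts in both libraries.

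The libraries were compared gene by gene with an exact two-sided binomial test on rounded expected counts, given the TMM effective library sizes, in genes with at least 10 counts in both together. Benjamini-Hochberg adjustment was applied at 0.05. Log2 ratios are replicate 1 over replicate 2 with 0.5 added to each count, so a negative value is higher in replicate 2. A list's median ratio was placed among 10000 random lists matched in 20 bins of expression, drawn from tested protein-coding genes outside the mitochondrial genome and from immunoglobulin and T cell receptor genes. That choice of genes was made after the data were seen. This compares these 2 libraries and not conditions. Tested on simulated data with 15118 genes, in which 100 genes were changed 2-fold and 100 genes 4-fold, the comparison recovered 74% and 91% of them. Among changed genes with over 100 counts it recovered 96.1% and 100%, and it called 10 unchanged genes. The simulated counts held counting error only, which is what the test assumes. The real libraries varied more, with a biological coefficient of variation of 0.164. These figures therefore check the calculation and give no error rate for the real libraries.

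The kallisto TPM was summed over each gene's transcripts and set against the RSEM TPM, with 0.1 added to each, in genes with a mean TPM of at least 1 by either quantifier. A gene counts as apart when it differs over 2-fold in the same direction in both libraries. Isoform shares are the leading transcript's percent of the gene's TPM by kallisto, with the RSEM share beside it.

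The named genes are, for each list, up to 4 members with the highest mean TPM and any member that goes against the rest of its list. They also include the 10 protein-coding and the 10 noncoding genes with the highest mean TPM. The rule further takes the 10 genes with the largest ratio between libraries among those past the binomial test with a mean of at least 100 counts, mitochondrial and spike-in entries left out. The last part takes the 10 genes with the largest quantifier difference at a mean TPM of at least 10. A gene named outside this rule is marked as chosen after its values were seen. Where a symbol has more than 1 entry (Aldoa and Rmrp), the highest entry was used. Il36g and Ahsp have no entry under that symbol and were not measured.

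The alternatives covered the quantifier, the unit (FPKM, and TPM over protein-coding genes alone), the pseudocount, the detection threshold, the filter on low counts, the scaling (DESeq2 size factors, library totals and ERCC counts), a fold minimum, the effective length and each replicate left out. The DESeq2 size factors were 1 and 1, because the median gene among those with counts in both libraries had equal rounded counts. No paired analysis was possible because there is 1 group. No test between the libraries with a dispersion was made, since there is 1 library a side. Expression from each parental genome was not analysed here, and the levels were not corrected for CAST/EiJ reads that differ from the reference.

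The versions used were Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.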

Results

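The data are total RNA-seq profiles of neutrophils from mouse spleen, as 1 group of 2 libraries. Replicate 1 held 18387963 expected counts and replicate 2 held 18090108. Values below are deposited TPM by RSEM, as mean ± SD with n = 2, unless another unit is named, and coordinates are mm10 with GENCODE M21 genes. The TPM of each library sums to the same total over all entries, noncoding ones included, so a library with more of 1 abundant RNA shows lower TPM for the other genes.

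The first comparison asks how the RNA classes divide each library. Protein-coding genes took 76.1% ± 5.28 of expected counts, with 72.4% in replicate 1 and 79.8% in replicate 2. Their share of TPM was 39.1% ± 8.90. The pair of 7SL RNA genes (Rn7s1 and Rn7s2, the RNA of the signal recognition particle) took 37.7% ± 8.66 of TPM and 8.44% ± 2.77 of counts. The 7SL share of TPM was 43.8% in replicate 1 and 31.6% in replicate 2. The 7SK RNA (Rn7sk) took 4.83% ± 1.32 of TPM. Mitochondrial ribosomal RNA took 5.06% ± 0.976 of counts. Small nuclear RNA took 6.52% ± 0.827 of TPM by RSEM, while kallisto gave 0.00755% in replicate 1 and 0.000335% in replicate 2. Long intergenic noncoding RNA took 5.99% ± 1.45 of counts, pseudogenes 0.868% ± 0.0577 and immunoglobulin genes 0.0394% ± 0.0162. The single entry Gm26917 held most of the long intergenic noncoding counts. It had 768621 of 1290240 in replicate 1 and 470133 of 897731 in replicate 2, so that share mainly reflects 1 entry. The class is the biotype of the annotation, and which RNA the Gm26917 reads came from was not tested.

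The 10 protein-coding genes with the highest level were S100a9, S100a8, Ngp, Actb, Lyz2, Ltf, Retnlg, Lcn2, Tmsb4x and Camp. Together they took 15.1% of the protein-coding TPM in replicate 1 and 20.7% in replicate 2. S100a9 (ENSMUSG00000056071.12, chromosome 3, 90692632 to 90695721) stood at 20494 ± 10320 TPM. S100a8 (ENSMUSG00000056054.9, chromosome 3, 90668978 to 90670035) stood at 15886.5 ± 9892 TPM. Ngp (ENSMUSG00000032484.8, chromosome 9, 110419747 to 110423012) stood at 6877 ± 2265 TPM. Levels of the other 7 fell from 6166 TPM for Actb to 2553 TPM for Camp. The 10 highest noncoding genes were Rn7s1, Rn7s2, Rn7sk, mt-Rnr2, mt-Rnr1, Gm26917, Rpph1, Gm23444, Gm23472 and Gm24407. Rn7s1 (chromosome 12, 69159295 to 69159594) and Rn7s2 (chromosome 12, 69361182 to 69361481) each stood at 188539 ± 43288 TPM, with equal values in each library. Their expected counts were equal too, with 956126 each in replicate 1 and 586665 each in replicate 2. The small nuclear RNA entries Gm23444 and Gm23472 also had equal values, 8922 ± 52.2 TPM each by RSEM against a mean of 3.85 TPM by kallisto. The separate levels of the genes within each of these pairs were therefore not resolved.

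The gene list comparison asks which neutrophil programmes were present and at what level. Of the 31 lists, 15 lay above and 4 below random lists of protein-coding genes. Lists not particular to neutrophils, such as glycolysis and the TCA cycle, were among the 15. A place above random lists therefore describes a level and does not by itself mark a neutrophil programme. The secondary granule list had a median of 1273 ± 401 TPM and the tertiary granule list 394 ± 68.3 TPM, both at the 100th percentile. The primary granule list had a median of 47.4 ± 12.01 TPM at percentile 99.7. The median was 147 ± 41.9 TPM for the surface receptors, 455 ± 107 TPM for the NADPH oxidase and 1325 ± 522 TPM for the calcium-binding and cytosolic defence proteins. Inflammatory cytokines and regulators had a median of 44.7 ± 11.7 TPM and myeloid transcription factors 42.9 ± 15.9 TPM, both above random lists. The interferon-stimulated genes, at 5.06 ± 2.70 TPM (percentile 55.9), and the extracellular trap and lytic death list, at 17.9 ± 6.28 TPM (percentile 90.1), lay within the range of random lists. The stefin A and Bcl2a1 paralogs had a median of 1.52 ± 0.138 TPM, also within that range, with Stfa2l1 highest at 21.5 ± 2.99 TPM.

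**Figure D1:**
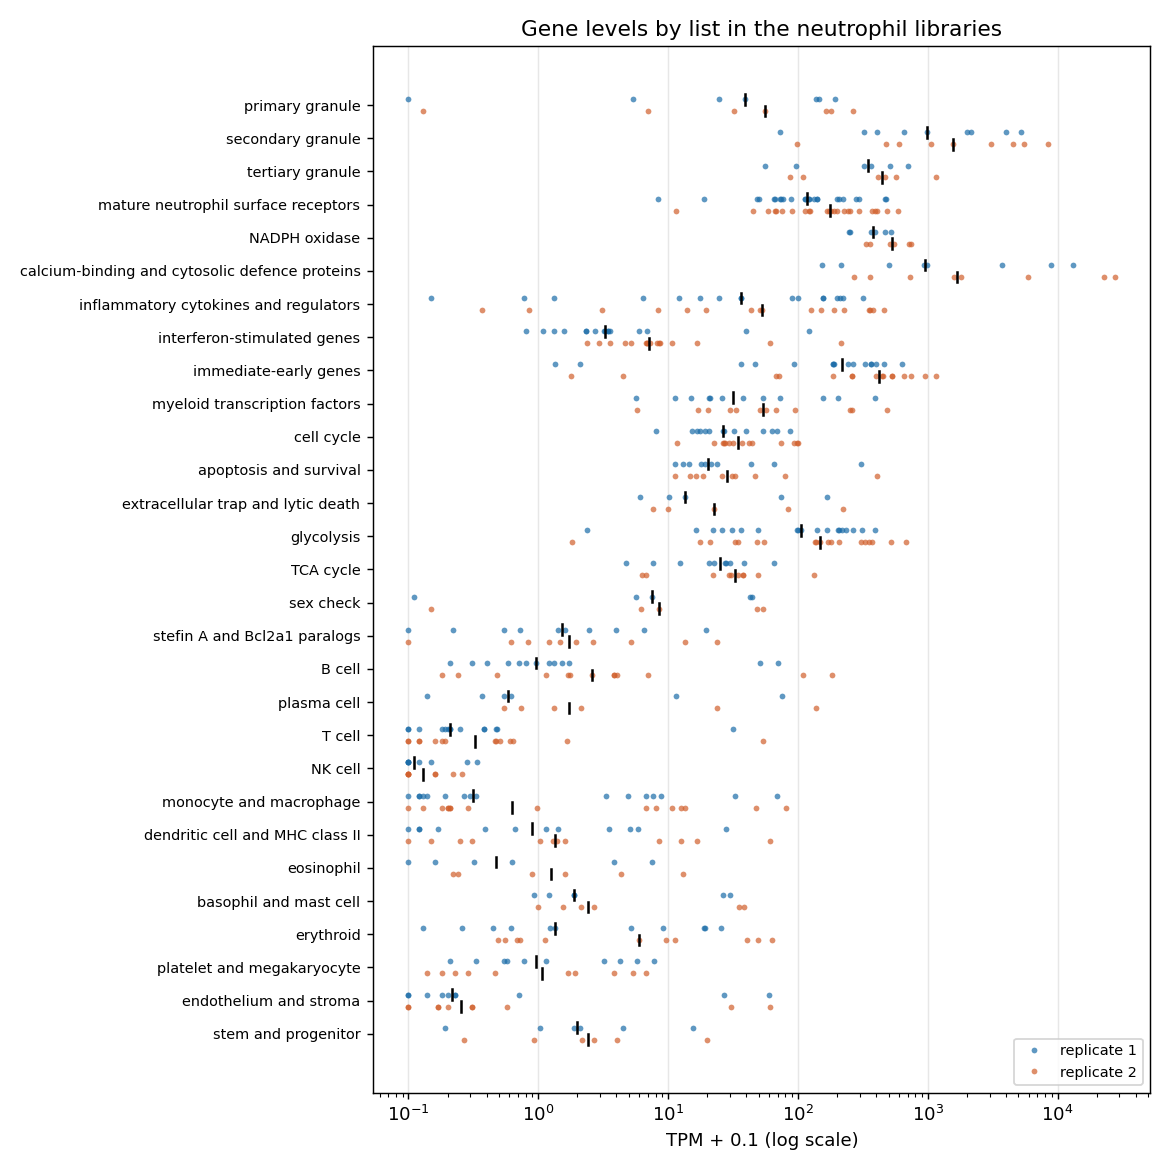
Each point is a gene's TPM + 0.1 (log axis) in 1 library, by gene list, and each black bar is the list's median in that library. The secondary granule list sits highest among the granule lists (989 and 1556 TPM) and the NK cell list lowest of all lists drawn (0.0100 and 0.0300 TPM).

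Within these lists the highest members were as follows. The secondary granule genes Ltf (chromosome 9, 111019271 to 111042767) and Lcn2 (chromosome 2, 32384633 to 32388252) stood at 4734 ± 1056 and 3340 ± 1682 TPM. The primary granule genes Mpo (chromosome 11, 87793581 to 87804413), Elane and Prtn3 stood at 229 ± 50.02, 159 ± 30.5 and 156 ± 13.5 TPM. Bpi went against its list, with 0 and 1 expected counts, where a count of 0 allows up to 3 counts. The tertiary granule genes Mmp9 and Adam8 stood at 938 ± 325 and 489 ± 30.3 TPM. Among the receptors, Csf3r was highest at 535 ± 81.4 TPM, followed by Il1r2 at 475 ± 12.8 TPM. Ncf1 led the NADPH oxidase list at 594 ± 173 TPM. Nfkbia led the cytokine list at 349 ± 42.8 TPM, in which Cxcl1 stood at 0.160 TPM. Mxd1 led the transcription factors at 439 ± 70.0 TPM. Ifitm3 led the interferon-stimulated genes at 168 ± 66.9 TPM and Padi4 the extracellular trap list at 196 ± 40.0 TPM. These SDs depend on the unit and do not rank genes by stability. With TPM over protein-coding genes alone, Ltf stood at 12108 ± 54.8 and Il1r2 at 1243 ± 250.

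The granule lists were compared in each library, since their genes are made at successive stages of neutrophil maturation. The secondary granule median exceeded the primary granule median by 4.73 ± 0.09 on the log2 scale. The tertiary granule median exceeded the primary one by 3.06 ± 0.12. The tertiary minus secondary difference was -1.67 ± 0.21. Each difference exceeded its spread between the libraries.

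The lists of cell state and structure were read the same way. Immediate-early genes had a median of 319 ± 145 TPM, with Fos highest at 900 ± 372 TPM and Egr3 and Egr2 lowest. The cell cycle list had a median of 30.4 ± 5.62 TPM (percentile 99.95), with Top2a at 92.6 ± 7.04 TPM and Mki67 at 84.8 ± 21.8 TPM. Apoptosis and survival genes had a median of 24.2 ± 5.77 TPM (percentile 98.95), with Mcl1 highest at 356 ± 68.9 TPM. Glycolysis genes stood at 127 ± 31.1 TPM and TCA cycle genes at 28.8 ± 5.43 TPM, both above random lists, with Pkm (456 ± 89.8 TPM) and Mdh2 (98.6 ± 47.7 TPM) highest. The structural and abundant noncoding RNA list had a median of 3988 ± 185 TPM and the isoform panel 333 ± 58.4 TPM. In the sex check list, at 7.87 ± 0.686 TPM, the Y-linked genes Ddx3y and Eif2s3y stood at 45.1 ± 4.04 and 49.2 ± 6.62 TPM and Xist at 0.0300 ± 0.0283 TPM.

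The markers of other lineages address what other cells of the spleen contributed RNA. The 46 genes of the granule and receptor lists had a pooled median of 138 TPM in replicate 1 and 195 TPM in replicate 2. The 117 genes of the 12 other-lineage lists had a pooled median of 0.470 and 0.820 TPM. The difference was 7.83 ± 0.14 on the log2 scale. Of the 117 genes, 61 lay below 1 TPM in both libraries and 16 at or above 10 TPM in both. List medians were 1.69 ± 1.17 TPM for B cells, 1.06 ± 0.817 TPM for plasma cells, 1.02 ± 0.311 TPM for dendritic cells and MHC class II, and 0.765 ± 0.552 TPM for eosinophils. They were 2.05 ± 0.364 TPM for basophils and mast cells, 3.53 ± 3.24 TPM for erythroid cells, 0.918 ± 0.0813 TPM for platelets and megakaryocytes, and 2.11 ± 0.318 TPM for stem and progenitor cells. These 8 lists lay within the range of random lists. The lists below that range were T cells at 0.168 ± 0.0813 TPM, NK cells at 0.0200 ± 0.0141 TPM, monocytes and macrophages at 0.373 ± 0.223 TPM, and endothelium and stroma at 0.135 ± 0.0283 TPM.

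Some members went against their list. Cd3d (ENSMUSG00000032094.8, chromosome 9, 44981786 to 44987339) stood at 42.5 ± 15.2 TPM, while Cd3e and Cd3g stood at 0.0950 and 0.280 TPM. The leading Cd3d transcript differed between the quantifiers and between the libraries, so its isoform was not settled. By kallisto Cd3d-203 took 4.01% of the Cd3d TPM in replicate 1 and 79.2% in replicate 2, and by RSEM 50.8% and 27.2%. Csf1r stood at 74.6 ± 8.44 TPM and Ccr2 at 40.0 ± 10.01 TPM, while C1qa stood at 0.155 TPM. Igkc stood at 126 ± 78.5 TPM, Igha at 106 ± 42.9 TPM and Ighm at 80.2 ± 41.0 TPM, while Cd79b stood at 4.05 ± 4.02 TPM. Mcpt8 and Prss34 stood at 32.4 ± 8.68 and 32.6 ± 3.76 TPM. Cd74 stood at 44.5 ± 23.5 TPM and Hba-a1 at 44.3 ± 27.0 TPM. Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) stood at 60.2 ± 1.27 TPM and Col1a2 (ENSMUSG00000029661.16, chromosome 6, 4504814 to 4541544) at 28.5 ± 2.51 TPM, while Col3a1 stood at 0.300 ± 0.240 TPM.

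The breadth of the transcriptome was counted at 1 TPM or more. Replicate 1 had 11551 such genes and replicate 2 had 11852. Both libraries shared 11074, of which 9528 were protein-coding, 511 pseudogenes, 145 long intergenic noncoding RNA genes and 135 small nuclear or nucleolar RNA genes.

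The agreement of the replicates sets the spread against which levels are read. Across 21474 genes, Pearson's r of log2(TPM + 0.1) was 0.958 and Spearman's rho was 0.928. The common biological coefficient of variation was 0.164 over 13089 genes. The chi-square of the counts of both libraries was 47.2 per degree of freedom, so the libraries differed by more than counting error.

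The spike-in RNA compares the libraries by what was added to each. ERCC entries took 0.341% ± 0.115 of expected counts and 0.410% ± 0.0951 of TPM. Their total was 1.65-fold higher in replicate 1, and 1.67-fold higher after TMM scaling, which is 0.74 on the log2 scale. Among 42 ERCC entries with at least 10 counts together, 37 were higher in replicate 1, and the median log2 ratio was 0.72.

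The gene-by-gene comparison asks where these libraries differ beyond counting error. Of 15118 genes tested with the exact binomial test, 4850 passed an adjusted p of 0.05, with 2273 higher in replicate 1 and 2577 higher in replicate 2. Among them 889 differed at least 2-fold, with 456 higher in replicate 1 and 433 in replicate 2. The split depends on the scaling and on the fold minimum. With ERCC scaling 11350 genes passed, of which 187 were higher in replicate 1 and 11163 in replicate 2, and the median ratio of all genes moved by -0.74 on the log2 scale. Of the 11350 genes, 3486 differed at least 2-fold. Ratios below use TMM scaling and are therefore relative to the bulk of genes.

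The 10 genes with the largest ratios by the naming rule all had expected counts that were not whole numbers, which means that reads were divided between genes. They were Gm28661, Gm15387, Gm42742, Gm10095, Gm10222, Pagr1a, Rpl15-ps3, Chtf8, Gm24497 and Gm28437. Gm28661 (chromosome 1, 24614885 to 24615565) had 2.28 expected counts in replicate 1 and 3498 in replicate 2, while kallisto gave 615 and 890 TPM. Gm42742 and Pagr1a, which overlap on chromosome 7, moved in opposite directions, with log2 ratios of -9.06 and 5.94. These ratios are uncertain for that reason. Among genes with whole counts, a restriction chosen after these values were seen, the largest ratio was that of Ccl2, with 44 counts in replicate 1 and 272 in replicate 2 (log2 ratio -2.60, adjusted p 4.05e-39 by the exact binomial test). It was followed by Iglc1 at -2.39, Hivep2 at -2.13, Bach2 at -1.85 and Pax5 at -1.77.

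The same ratios were summarised for the 29 lists with at least 3 tested genes outside the noncoding RNA list. The medians of 16 lists lay below and that of 1 list above matched random lists. The random lists were matched on expression and not on gene length or GC content. The interferon-stimulated genes had a median log2 ratio of -0.95, where the central 95% of random lists ran from -0.23 to 0.15. All 15 tested members were higher in replicate 2, both over all genes tested and adjusted over the list alone. Among them Ifit1 and Ifit3 had ratios of -2.05 and -1.94. The immediate-early genes had a median of -0.56, with 15 of 16 members higher in replicate 2, and the same 15 count adjusted over the list alone. The calcium-binding and cytosolic defence list stood at -0.55 (8 of 8) and the secondary granule list at -0.41 (9 of 9). Medians were -1.27 for B cells, -1.05 for the erythroid list, -0.88 for eosinophils, -0.82 for plasma cells and -0.81 for dendritic cells and MHC class II. The receptors stood at -0.21, with 18 members higher in replicate 2 and 3 in replicate 1, or 19 and 3 adjusted over the list alone. The other lists below random lists were NADPH oxidase (-0.34), monocytes and macrophages (-0.29), cytokines (-0.28), cell cycle (-0.25), myeloid transcription factors (-0.24) and the TCA cycle (-0.24). NADPH oxidase and the TCA cycle fell inside the random range with deposited TPM and with kallisto TPM, and the transcription factors and the monocyte list did so with kallisto TPM alone. The platelet and megakaryocyte list had a median of 1.27, above random lists, with 5 members higher in replicate 1 and 1 in replicate 2, or 6 and 1 adjusted over the list alone. Its members had few counts, such as 66 and 33 for Pf4 and 223 and 93 for Itga2b. The tertiary granule list (-0.29), the primary granule list (-0.12), glycolysis (-0.12), apoptosis (-0.07), the extracellular trap list (-0.10), the isoform panel (-0.11), the stefin list (-0.16) and T cells (-0.38) lay within the random range, as did the sex check, basophil, endothelium and stem lists.

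**Figure D2:**
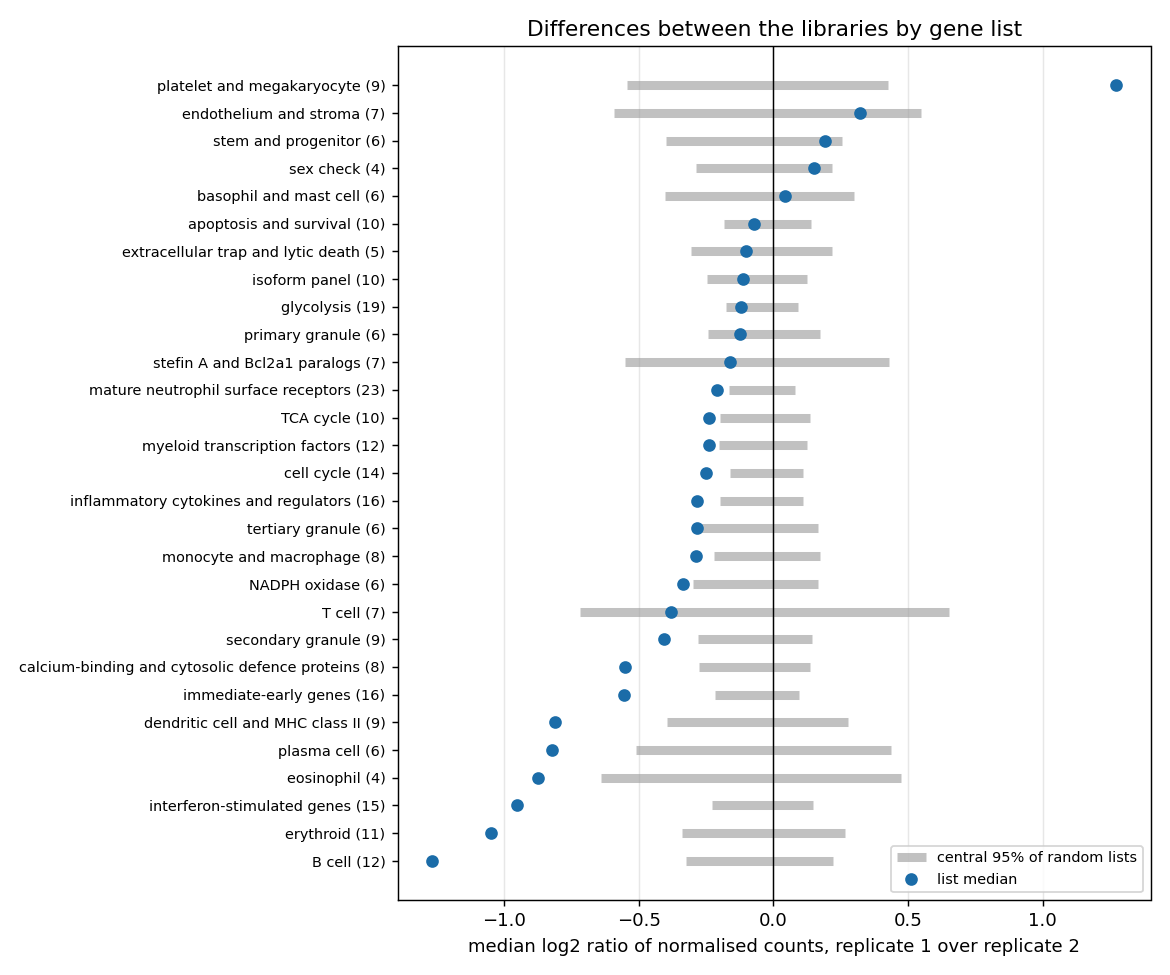
Points are list medians of the log2 ratio of normalised counts, replicate 1 over replicate 2, grey bars are the central 95% of matched random lists, and the number of genes tested is in parentheses. The B cell list (-1.27) and the platelet list (1.27) mark the ends, with TMM scaling; ERCC scaling shifts every point by -0.74, and the platelet median stays positive at 0.53.

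The quantifier comparison asks which gene levels depend on how reads were assigned. Of 13328 genes, 1753 (13.2%) differed over 2-fold in both libraries, with 1326 higher by kallisto and 427 higher by RSEM. Among 10370 protein-coding genes 435 differed (4.19%). Among the 255 members of the fixed lists with a mean TPM of at least 1 by either quantifier, 2 differed in both libraries, Eno1 and Il5ra. Members apart in 1 library alone are not counted. Rmrp had 7404.5 and 0 TPM by kallisto against 4308 and 4145 TPM by RSEM. In replicate 2 Rac2 had 337 TPM by kallisto and 746 TPM by RSEM. The share differing in both libraries was 61.8% of long intergenic noncoding RNA genes, 70.3% of small nuclear RNA genes and 78.3% of small nucleolar RNA genes. The 10 largest differences by the naming rule were Gm24407, Gm24265, Gm22988, Gm23238, Gm26447, Gm24497, Gm24727, Gm25679 and Gm22068, higher by RSEM, and Gm19220, higher by kallisto. Gm24407 has an effective length of 41 nt and had 6702 and 3899 TPM by RSEM, against 0 in both libraries by kallisto. The processed pseudogene Gm19220 had 0 TPM by RSEM and 4527 and 2279 TPM by kallisto. Of the protein-coding genes, chosen after their values were seen, Gm47283 was 0 by RSEM and 233 and 216 TPM by kallisto, and mt-Atp8 was 650 and 493 TPM by RSEM and 4.20 and 0 TPM by kallisto.

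**Figure D3:**
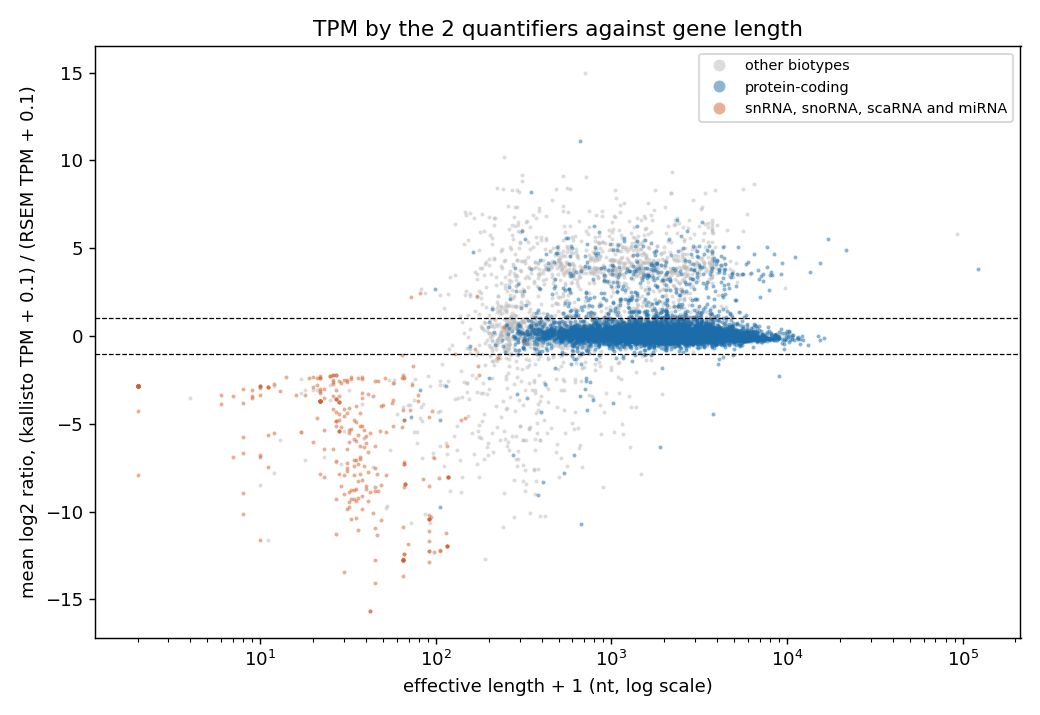
Each point is a gene, with effective length + 1 in nt on a log axis and the mean log2 ratio of kallisto to RSEM TPM, 0.1 added to each; dashed lines mark 2-fold. Most small RNA genes lie at short lengths and below the lower line, while 4.19% of protein-coding genes differ over 2-fold in both libraries.

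Isoform shares were read for 10 genes. In 7 the leading transcript was the same by both quantifiers. Pkm-201 took 88.2% ± 0.820 of the Pkm TPM, Cdc42-202 84.1% ± 0.0633, Il1rn-201 76.6% ± 1.98, Mcl1-201 63.3% ± 2.496, Cd44-203 35.6% ± 0.701, Tpm3-201 35.2% ± 4.46 and Ptprc-203 32.2% ± 3.46 by kallisto. In 3 genes the quantifiers named different leading transcripts. For Csf3r, kallisto gave Csf3r-202 49.0% ± 2.99 and RSEM gave Csf3r-201 65.1% ± 1.81. For Myl6, kallisto gave the retained-intron transcript Myl6-212 66.8% ± 7.44, and RSEM gave Myl6-201 84.4% ± 3.70. For Cflar, kallisto gave Cflar-210 28.5% ± 0.370, and RSEM gave Cflar-208 20.5% ± 0.959.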

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

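No test in this part was chosen after its result was seen. Entries outside the measured genes held counts above the 3 that a count of 0 allows. The phiX entry, a sequence used as a control in sequencing runs, had 70 expected counts in replicate 1 and 50 in replicate 2, which is 0.000381% and 0.000276% of counts. The 26248 tRNA entries together had 38.7 expected counts in replicate 1 and 9.7 in replicate 2. Of these entries 26185 have an effective length of 0 and held no counts, so the counts lie on the other 63 and say nothing about most tRNA. The libraries hold no control sample against which these counts can be set, and their source was not tested.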

How the results depend on the processing

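The length and GC correction and the count of detected genes over 300 nt of effective length were chosen only after the main values were seen, and all other alternatives in this part were planned.

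With kallisto TPM the secondary minus primary granule difference was 4.45, the tertiary minus primary difference 2.81 and the neutrophil minus other-lineage difference 7.66, each further from the main value than 1 SD and in the same direction. The cause was not tested. FPKM and TPM over protein-coding genes alone left these 3 differences within 1 SD. That says little, as each rescales a library by 1 factor, which all but cancels within it. A pseudocount of 1 left the granule list differences within 1 SD. Leaving out 1 replicate gave 4.67 to 4.80, 2.98 to 3.15 and 7.73 to 7.92. With 2 libraries such values stay within 1 SD by construction. The counts of 15 lists above and 4 below random lists held with kallisto TPM, FPKM, protein-coding TPM and either replicate left out. Protein-coding TPM, higher by construction, moved 156 of 160 named genes and 31 of 31 list medians beyond 1 SD. Kallisto moved 30 and 6, FPKM 27 and 4. Of 145 named genes at 1 TPM or more, kallisto placed 137 within 2-fold of RSEM.

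The number of genes detected fell to 7301 at 5 TPM, since fewer genes pass a higher threshold. The other definitions gave 10634 (over 300 nt) to 15381 (0.1 TPM), and single libraries 11551 and 11852. Pearson's r was 0.981 with a pseudocount of 1 and 0.982 over protein-coding genes at 1 TPM or more, where Spearman's rho was 0.981. The coefficient of variation was 0.189 without a filter and 0.137 at 100 counts. These values have no spread of their own to be judged by, and low counts weigh less in the alternatives with the higher r.

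Genes that differ between the libraries numbered 11350 with ERCC scaling and 889 with a 2-fold minimum, against 4850. The rise under ERCC scaling follows from its construction, which moves all ratios by -0.74. With it 187 genes were higher in replicate 1 and 11163 in replicate 2, and 1383 of the 4850 passed the threshold with the opposite sign, while 2764 passed with the same sign. With DESeq2 size factors, library totals and no filter, 0 passed with the opposite sign. DESeq2 size factors gave 4700, library totals 4896 and no filter 4567. Higher in replicate 2 were 53.1% of the calls in the main comparison, 57.4% with DESeq2, 62.2% with totals, 53.7% without a filter, 98.4% with ERCC and 48.7% with the 2-fold minimum (456 higher in replicate 1 and 433 in replicate 2), so the majority depends on the setting.

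List medians between libraries changed side for 5 lists. NADPH oxidase (-0.50 with deposited TPM, -0.48 with kallisto) and the TCA cycle (-0.39, -0.49) fell inside the random range with both. Myeloid transcription factors (-0.51) and monocytes and macrophages (-0.55) did so with kallisto, and the stefin list (-0.80) fell outside it. The cause was not tested. Lists below random lists numbered 14 and 13 under these units, against 16. ERCC scaling is 1 factor for every gene, so it says nothing about the place of a list among random lists. The sex check, basophil, endothelium and stem lists, which were not called, had medians below 0 with deposited TPM and kallisto TPM and above 0 in the main comparison. ERCC scaling lowers every median alike, so signs below 0 under it say nothing. The platelet median was 0.75 with deposited TPM, 0.61 with kallisto TPM and 0.53 with ERCC scaling, against 1.27.

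Genes higher by RSEM fell from 427 to 122 over 300 nt. All genes apart numbered 1282 to 1416 under the alternatives. By RSEM the shares were Ptprc-203 43.2%, Cd44-203 38.8%, Pkm-201 86.7%, Mcl1-201 80.8%, Il1rn-201 64.1%, Csf3r-202 14.3%, Myl6-212 8.15%, Cdc42-202 84.4% and Cflar-210 17.2%, each further than 1 SD from kallisto (Tpm3-201 was within it), and the cause was not tested. Genes under 10 counts in both libraries together, where depth limits the test, entered only the comparison without a filter, with 21415 genes tested against 15118.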

Other observations

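The tests below on lower purity, the collagen sources, shared reads, near-identical copies and short transcripts were chosen only after the results were seen, as were all gene families and the other units read for them. The tests on length and GC content, on the opposite strand and on the same strand were written before theirs. With 1 group, no biological explanation within the neutrophils was tested for any pattern, and the tests of cell sources concern RNA of other cells. CAST/EiJ reads that differ from the reference were not tested either.

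The interferon-stimulated genes were higher in replicate 2, with a median log2 ratio of -0.95. After the medians of length and GC bins were removed, the median was -0.91, outside the -0.18 to 0.18 of random lists, and 15 of 15 genes were higher in replicate 2. This argues against length or GC content as the whole cause. The libraries also differed in composition. Protein-coding genes took 72.4% of counts in replicate 1 and 79.8% in replicate 2, and ERCC counts were 1.67-fold higher in replicate 1 after TMM scaling. With TMM scaling Gm42418 and Lars2, chosen after their values were seen, were 1.88-fold and 1.71-fold higher in replicate 1, but with ERCC scaling only 1.12-fold and 1.02-fold. A shift shared by all protein-coding genes moves the random lists as well, so it does not set this list apart, but whether the composition and the interferon difference have a common source was not tested. A lower share of neutrophils in replicate 2 would raise the markers of every other lineage alike only if the mix of other cells stayed the same. The platelet list stood at 1.27, higher in replicate 1, and the B cell list at -1.27. With deposited TPM these medians were 0.75 and -1.24, and with kallisto TPM 0.61 and -1.48, so the platelet difference is smaller in those units and in the same direction. Of 11 other-lineage lists tested, 6 lay below and 1 above random lists. The prediction was written with the platelet and B cell medians known, so its outcome is no independent test. As values, these medians argue against lower purity with an unchanged mix of other cells. The platelet side rests on 1 list whose members had few counts. Lower purity with a change in that mix stays open. Among the neutrophil lists, secondary granules (-0.41) and receptors (-0.21) were higher in replicate 2. The primary (-0.12) and tertiary (-0.29) granule lists lay within the random range. A difference in handling, in cell state or between animals may also account for the interferon difference, and none of these was tested.

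Col1a1 and Col1a2 stood far above Col3a1. Of their 4 expected counts, 0 were not whole, with 7486 and 6588 for Col1a1, which argues against reads divided with other genes. The lists, their division into a stromal and a bone-forming list, and the bound of 10% of the Col1a1 TPM were all chosen after the levels were seen. An earlier version left out Fn1 and Vim, and both exceed Col1a1 at 367 and 613 TPM, but cells of the neutrophil lineage and other leukocytes express them too. The median of 13 genes of collagen-producing stromal cells was 1.13% of the Col1a1 TPM in replicate 1 and 1.57% in replicate 2. In that list 10 genes lay under 10% in both libraries. The genes and the bound were chosen with the levels known, so this does not decide whether such cells were the source. The median of 5 genes of bone-forming cells was 7.35% and 10.02%, on both sides of the bound, with Sparc at 10.1 TPM and Bglap at 10.8 TPM highest. Runx2, left out of that list and chosen after its values were seen, stood at 21.7 TPM. Bglap had 45.9 and 95 expected counts, more in replicate 2, where Col1a1 had fewer. The lists share Sparc and Serpinh1. Stromal cells, bone-forming cells and transcription in the neutrophils themselves cannot be told apart from these values. The bound was chosen after the levels were seen, and the bone-forming median lies at it. The labels name no sort or gate.

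Genes over 4-fold higher by kallisto numbered 1044, with 264 protein-coding genes, 239 long intergenic noncoding RNA genes, 180 entries of the TEC biotype, 134 processed pseudogenes and 92 antisense genes. If kallisto had counted reads of the opposite strand, more of these genes than of matched genes would overlap a gene expressed at 10 TPM or more on that strand. The share was 4.98%, below the 6.61% to 9.77% of matched draws and the 6.13% to 9.20% of draws matched also on span. For an overlapping gene on the same strand the share was 3.07%, against 7.66% to 10.7%, and 11.7% to 15.2% with span. Both argue against overlap with genes at 10 TPM or more as the main source. Overlapping genes below 10 TPM were not counted, so the test says nothing about them. The span-matched draws were added after the first result. Near-identical copies were sought through expected counts that were not whole. The share was 6.61%, below the 12.9% to 16.9% of matched draws. The test decides nothing, because a count of 0 is whole whether or not reads were divided, and 49.6% of these genes had RSEM counts under 0.5 in both libraries. That reading was adopted after the result was seen, since an earlier rule set this aside only when over 50% of the genes had such counts and would have counted the share against this explanation. Near-identical copies may therefore remain.

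Genes over 4-fold higher by RSEM numbered 372, with 116 processed pseudogenes, 93 small nucleolar, 45 small nuclear and 43 micro RNA genes. Their median effective length was 74 nt, where random genes had 1616 to 1920 nt, and 261 lay under 200 nt. This is consistent with short transcripts as a candidate cause. How either quantification handles them was not tested.

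A total of 12 gene families, chosen after seeing the values, were read against matched random lists with TMM scaling. The length and GC correction was made for the interferon-stimulated genes alone. Length or GC bias was therefore not tested for these families or for the other lists. Replication-dependent histone genes had a median log2 ratio of -0.56, with 56 of 63 higher in replicate 2, and took 2.69% and 3.39% of protein-coding TPM. Cytosolic ribosomal protein genes stood at -0.36, with 64 of 82 higher in replicate 2. Cathepsin genes stood at -0.46, guanylate-binding and interferon-inducible GTPase genes at -0.77, Slfn genes at -0.32, mitochondrial ribosomal protein genes at -0.17, proteasome genes at -0.12 and heat shock genes at -0.12, all below random lists. In the last 3 families few members passed as higher in replicate 2, with 18 of 75, 11 of 37 and 16 of 61. Higher in replicate 1 were 1, 0 and 7. Class I MHC genes at -0.19, integrin genes at -0.05 and olfactory receptor genes at 0.55 lay within the range. With deposited TPM the same families lay outside and inside the range. With kallisto TPM the Slfn genes fell inside it (percentile 3.36) and the integrin genes lay above it (percentile 99.1), although their median stayed below 0 at -0.10. The olfactory median was -0.20 with ERCC scaling and about 0 with kallisto TPM. ERCC scaling moves every gene alike and cannot change a place among random lists. Mitochondrial protein-coding genes, without a list test, took 1.81% and 1.38% of protein-coding TPM. Of the olfactory receptor genes, 0 of 1093 reached 1 TPM in both libraries.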
